A study of Homo sapiens with 8 samples.

How the data were processed

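The series holds 8 RNA-seq libraries of xenograft tumours grown from VCaP, an established human prostate cancer cell line that carries the TMPRSS2-ERG fusion and responds to androgen. Per the labels' protocols, the tumours grew in intact male ICR SCID mice to 500 mm3 and were then biopsied, after which the mice were castrated. A relapsed tumour was biopsied again, and the mice then received abiraterone, an inhibitor of androgen synthesis, and enzalutamide, an antiandrogen, until the next relapse. The libraries fall into 3 groups by the condition label, namely before castration (Pre-Cx, n = 2), castration-resistant relapse (CRPC, n = 2) and relapse on both drugs (Abi/Enza-resistant, n = 4). They come from 4 tumours, C3-1, C1-4, C1-3 and C2-17, so that the libraries of a group come from separate tumours. Biopsies were fixed in 10% formalin for 24 h and embedded in paraffin, and total RNA was extracted from 5 ribbons of 10 micron per tumour, per the labels' protocols.

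The authors deposited 1 file of raw counts per library, with a whole-number read count for each Ensembl gene identifier and no normalization. The submitters' processing notes name FastQC, Trimmomatic, cutadapt, TopHat2 and HTSeq, without versions, and the human build hg19, also called GRCh37. The annotation release, the strand setting of the counting, the library kit and any step that removes mouse reads are not given in the sources used here. Reads from the mouse host that align to the human genome can therefore be part of a count. Whether reads of a gene and its antisense partner were told apart is not known. The 5 summary lines that name no gene were left out of library sizes and tests. Of the alignments listed per library, 19352247 to 27678669, 21.2% to 25.2% fell in genes, 57.9% to 62.2% in no feature, 14.7% to 17.3% were not unique and 0.480% to 0.566% were ambiguous between genes. Reads that align to several places are counted apart, so members of multigene families, such as KLK2 and KLK3, the UGT2B, AKR1C, metallothionein, HLA and olfactory receptor genes, and GAPDH with its pseudogenes, can be undercounted or hold reads of a close copy, and their values are uncertain to that extent. The 13 mitochondrially encoded mRNAs have 0 counts in all 8 libraries, so nothing can be said of them.

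The libraries hold 4105435 to 6396196 counts in genes, and 24910 to 26281 genes have at least 1 count. A gene with 3 counts in 1 library has 0.469 to 0.731 CPM (counts scaled to the same library total). Such floors and all counting intervals, at the 95% level, cover counting error only, since reads without molecular identifiers are not independent molecules. Of 44285 identifiers, 34957 matched a symbol, and these hold 89.3% of the counts. The other 9328 kept their identifier. The reference annotation was of another build, GRCh38, so no coordinates are given, and that annotation served only for symbols, gene types (18276 protein-coding identifiers) and the order of neighbouring genes. No pair of libraries held identical values, and the chi-square per degree of freedom between libraries of a group ran from 3.85 to 15.8, above counting noise.

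Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on the counts, with TMM scaling, the default filter on low counts by group and 1 coefficient per group over all 8 libraries. The filter left 17168 genes. The groups shared one estimate of the spread, with 5 residual and 6.35 prior degrees of freedom and a biological coefficient of variation of 15.9%. Adjusted p is by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Every adjusted p given for a gene comes from this test unless another is named. Levels are CPM, with mean and SD over the libraries of a group, and log2 fold changes have a standard error (SE) from the fit. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 8 protein-coding genes with the largest increase and the 8 with the largest decrease among called genes with a mean count of at least 50 and no overlap between the libraries of both groups. It adds 12 genes fixed by name (among them KLK3, TMPRSS2, ERG, FKBP5, CYP17A1, AKR1C3, NR3C1, DPP4, MKI67 and CHGA) and, for each list described, the up to 4 members with the smallest p. Some genes that the rule takes are left out of the text, the figures and the comparison of single libraries within a group, but stay in the counts of genes and in the lists. Genes outside this rule are said to be chosen after their values were seen.

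The 26 lists cover androgen-induced and androgen-repressed genes, steroid metabolism, glucocorticoid-induced genes, S-phase, mitosis, neuroendocrine, luminal and basal markers, epithelial-mesenchymal transition, genes associated with ERG, interferon response, hypoxia and glycolysis, cholesterol and fatty acid synthesis, the unfolded protein response, oxidative phosphorylation, Wnt targets, immediate early genes, ribosomal proteins, mitochondrially encoded mRNAs and markers of fibroblasts, endothelium, leukocytes, muscle, erythroid cells and adipocytes or skin. With at least 3 tested members, 24 of them entered camera (limma 3.58.1), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 24 lists. The lists were also tested with an estimated correlation and with fry, whose directional test asks whether the genes of a list move, on balance, one way, without comparing them with other genes. A list level is the mean log2 CPM over its tested members, with a prior count of 2.

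Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts, a filter at a mean of 5 CPM, the tumour as a block or as a random effect, limma-voom, only the groups compared, protein-coding genes only, leaving out each library in turn, and a batch term. The batch term stands for 2 naming patterns of the deposited files, one holding Pre-Cx C3-1 and CRPC C3-1 and the other the other 6 libraries. The labels do not say whether these patterns mark a batch. Within each pattern Pre-Cx and CRPC have 1 library each, and no fit within a pattern was made. In both groups the pattern splits tumour C3-1 from the other tumour, so a batch and a tumour effect cannot be told apart there. All 4 Abi/Enza-resistant libraries share one pattern. Leaving out Abi/Enza-resistant C3-1 and CRPC C3-1 together is an alternative chosen after seeing the data.

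The tumour labels pair biopsies of the same tumour, by the labels: Pre-Cx and CRPC share C3-1, CRPC and Abi/Enza-resistant share C3-1 and C1-3, and Pre-Cx and Abi/Enza-resistant share C3-1 and C1-4. The deviations from the group means, correlated across genes, which are not independent replicates, were 0.0225 for the first pair, 0.107 and 0.0280 for the next pairs, and -0.0547 and 0.0331 for the last. In groups of 2 libraries the deviations are mirror images, so these correlations cannot show that pairing is absent. The tumour labels pair only part of the libraries, and a block leaves 2 residual degrees of freedom. For that reason the fit with the tumour as a block was planned as an alternative, given beside a result where it changes the call.

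The tests were run on simulated counts with known changes. Apart from these changes the simulated libraries shared one mean and one spread per gene. None was set apart as Abi/Enza-resistant C3-1 is in the data, so the shares below need not hold for the real comparisons. At a log2 change of 1, 32.0% of 197 changed genes were called in the simulated comparison of CRPC with Pre-Cx, 53.5% of 200 in that of Abi/Enza-resistant with CRPC and 58.3% of 192 in that of Abi/Enza-resistant with Pre-Cx. At a log2 change of 2 these shares were 81.8% of 198, 91.9% of 198 and 95.3% of 192. Unchanged genes made up 5.95% to 9.01% of the calls, in 16834 to 16862 genes tested. An exact permutation test of a single value cannot go below a p of 1/3 with 2 against 2 libraries or 1/15 with 4 against 2, so none is given. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.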

Results

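The transcriptome of VCaP xenografts was read at 3 stages of androgen deprivation, in 2 biopsies before castration, 2 of tumours that had relapsed after castration and 4 of tumours that had relapsed on abiraterone with enzalutamide. Counts in genes were 4508795 and 5405963 in Pre-Cx C3-1 and C1-4, 4105435 and 4625001 in CRPC C3-1 and C1-3, and 4235791, 6396196, 5157325 and 5765822 in Abi/Enza-resistant C2-17, C3-1, C1-3 and C1-4. The largest component of the log2 CPM, with 42.5% of the variance, set the Pre-Cx libraries at -52.3 and -60.0 and the other 6 between 3.61 and 31.1. The next one, with 19.8%, set Abi/Enza-resistant C3-1 at 55.9, with the other 7 between -17.8 and 9.99.

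The first comparison asks what differs between tumours relapsed after castration and tumours before it. DPP4 (ENSG00000197635), a cell-surface peptidase that cleaves incretin hormones, fell from 148 ± 5.93 CPM in Pre-Cx (SD, n = 2) to 2.68 ± 0.75 CPM in CRPC (SD, n = 2), a log2 change of -5.76 ± 0.43 (SE, adjusted p = 8.2e-05). The list of androgen-induced genes lay lower, with 15 of 42 tested genes called lower and 2 higher, and the androgen-repressed list lay higher. Genes of DNA replication and mitosis lay lower as lists, with a median log2 change of -0.79 and -0.98 and 12 of 29 and 8 of 30 members called. Both list calls were lost with an estimated correlation (adjusted p = 0.361 for each), and with the tumour as a block 1 and 0 members were called.

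In all, 595 genes were called, 241 higher and 354 lower in CRPC, of which 186 and 231 changed more than 2-fold, and 2939 genes had an unadjusted p under 0.05. All 595 showed no overlap between the libraries of both groups, a state found in 52.6% of all tested genes and given by chance to 33.3%. With no filter on low counts the test called 1596 genes, and with only the libraries of both groups 1974. With the tumour as a block it called 156 genes, 144 of them among the 595. The count was 143 without Pre-Cx C3-1, 58 without Pre-Cx C1-4, 79 without CRPC C3-1, 177 without CRPC C1-3 and 1588 without Abi/Enza-resistant C3-1, and it was 788 without CRPC C3-1 and Abi/Enza-resistant C3-1 together, a choice made after seeing the data.

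**Figure D1:**
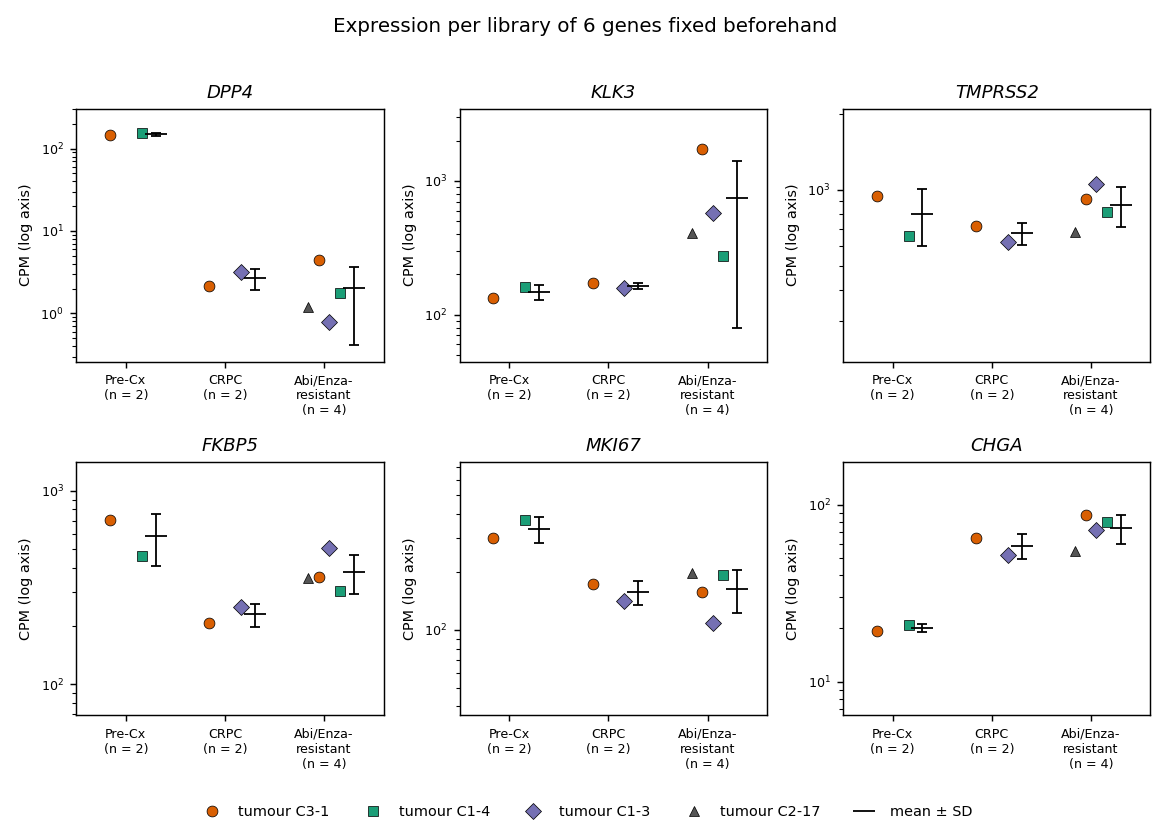
CPM on a log axis of 6 genes fixed beforehand in each of the 8 libraries, with tumours as symbols and the mean ± SD of each group beside them. KLK3 in Abi/Enza-resistant C3-1 reaches 1736 CPM.

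The largest increases among abundant coding genes included those of GRIA2 (log2 change 7.57 ± 0.89), a subunit of AMPA-type glutamate receptors, with 4 reads in both Pre-Cx libraries and 716 in both CRPC libraries, OR51E1 (4.32 ± 0.84), an olfactory receptor known from the prostate, and TMEFF2 (4.19 ± 1.03), a transmembrane protein of prostate and brain. OR51E1 lies in a stretch of 13 neighbouring genes that were higher over the pooled libraries after castration, and its family shares sequence. SDC2 (3.75 ± 0.37), a heparan sulfate proteoglycan, ADAM7 (2.96 ± 0.32), VWA5B1 (2.91 ± 0.28) and PTGER2 (2.91 ± 0.46), a prostaglandin E receptor, followed. The largest decreases after DPP4 were those of TESC (-4.37 ± 0.76), a calcium-binding protein, SPOCK2 (-3.62 ± 0.35), a matrix proteoglycan, STEAP4 (-3.46 ± 0.25), a metalloreductase, ESRRG (-2.92 ± 0.35), an orphan nuclear receptor, and HLA-DMA (-2.88 ± 0.37), which loads peptides on class II molecules. ELOVL2 (-2.67 ± 0.26), of polyunsaturated fatty acid elongation, fell too. The highest adjusted p of these was 0.0489, for TMEFF2. With the tumour as a block, OR51E1 (adjusted p = 0.083), TMEFF2 (0.159), PTGER2 (0.064) and TESC (0.114) had changes of 4.01, 3.93, 2.99 and -4.24 and were not called. The same 4 calls were lost without either Pre-Cx library or CRPC C3-1, and all but that of PTGER2 without CRPC C1-3, at an adjusted p of up to 0.230, 0.346 and 0.126 for the first 3 (without Pre-Cx C1-4) and 0.152 for TESC (without CRPC C3-1). That of TMEFF2 was lost also with the batch term (0.086), without Abi/Enza-resistant C2-17 (0.080) and without Abi/Enza-resistant C1-4 (0.072). Of the 35 called genes that the rule takes for this comparison, 13 kept their call without each library in turn, among them GRIA2, DPP4 and STEAP4, against 14 without Pre-Cx C3-1, 14 without Pre-Cx C1-4, 13 without CRPC C3-1 and 18 without CRPC C1-3. With the block 17 of them lost their call, at an adjusted p of 0.0610 to 0.299, and over all alternatives the adjusted p of these 17 ran from 1.5e-51 to 0.346.

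Of 42 tested androgen-induced genes, 15 fell and 2 rose, or 18 and 5 adjusted over the list alone (camera adjusted p = 1.7e-13, and 0.0065 with an estimated correlation). STEAP4, NCAPD3 (-1.58 ± 0.15), a condensin subunit, and ACSL3 (-1.38 ± 0.16), an acyl-CoA synthetase, fell, as did FKBP5 (-1.34 ± 0.25, adjusted p = 0.015), a co-chaperone of steroid receptors, while ADAM7 and, chosen after its values were seen, STEAP2 (1.01 ± 0.20, adjusted p = 0.019), a metalloreductase, rose. The call of STEAP2 was lost with the tumour as a block (adjusted p = 0.111, with a range over alternatives of 2.5e-07 to 0.244) and without Pre-Cx C3-1 (0.060), Pre-Cx C1-4 (0.244), CRPC C3-1 (0.158) or CRPC C1-3 (0.085), and that of FKBP5 without Pre-Cx C3-1 (0.122), CRPC C3-1 (0.195) or CRPC C1-3 (0.083). KLK3, which encodes prostate-specific antigen, stood at 147 ± 19.0 CPM in Pre-Cx and 165 ± 8.88 in CRPC (log2 change 0.16 ± 0.65, adjusted p = 0.935). TMPRSS2 (-0.26 ± 0.22, adjusted p = 0.620) and its fusion partner ERG (-0.14 ± 0.17, adjusted p = 0.751) were not called either. With the tumour as a block 10 members fell and 1 rose.

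Of 9 tested androgen-repressed genes 2 rose, among them TRIB1 (1.56 ± 0.22, adjusted p = 0.0041), a pseudokinase, or 3 adjusted over the list alone (camera adjusted p = 4.5e-07, and 0.031 with an estimated correlation). CAMK2N1, an inhibitor of a calcium-dependent kinase, had a change of 1.26 ± 0.44 (adjusted p = 0.164), and OPRK1, an opioid receptor, of 0.64 ± 0.30 (adjusted p = 0.312). Without Abi/Enza-resistant C3-1, CAMK2N1 was called (adjusted p = 0.0023), and TRIB1 was not without Pre-Cx C3-1 (0.061), CRPC C3-1 (0.059) or Pre-Cx C1-4 (0.054). AKR1C3, an enzyme of androgen synthesis, stood at 11.5 ± 1.43 and 17.8 ± 5.66 CPM (0.65 ± 0.44, adjusted p = 0.509) and NR3C1, the glucocorticoid receptor, at 9.69 ± 1.09 and 18.0 ± 8.24 CPM (0.88 ± 0.64, adjusted p = 0.540). CYP17A1, the target of abiraterone, had 4 reads in Pre-Cx and 1 in CRPC and was not tested.

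Of 29 tested genes of S-phase 12 fell, or 23 with 1 higher adjusted over the list alone, and of 30 of mitosis 8 fell, or 29 adjusted over the list alone. The camera adjusted p was 1.1e-18 and 1.7e-22, and both calls were lost with an estimated correlation (adjusted p = 0.361 for each) and with fry (0.060 and 0.089). Examples were TK1 (-1.25 ± 0.19), of thymidine salvage, MCM6 (-1.02 ± 0.18), of the replicative helicase, RRM2 (-0.93 ± 0.19), of ribonucleotide reduction, BRCA1 (-0.90 ± 0.16), of DNA repair, TPX2 (-1.17 ± 0.21), AURKA (-0.90 ± 0.19), BUB1B (-1.05 ± 0.21) and HMMR (-1.36 ± 0.29), all of the spindle or its checkpoint, and the proliferation marker MKI67 (-1.10 ± 0.25, adjusted p = 0.036). With the tumour as a block, 1 gene of S-phase and 0 of mitosis were called, and of these examples TK1 kept its call while the adjusted p of the others lay between 0.061 and 0.180. All of these examples lost their call without CRPC C3-1 and without Pre-Cx C1-4, all but TK1 without Pre-Cx C3-1, and all but MCM6 without CRPC C1-3. The highest adjusted p came without Pre-Cx C1-4 for TK1 (0.093), BRCA1 (0.155), TPX2 (0.164), AURKA (0.298) and HMMR (0.298), without CRPC C3-1 for MCM6 (0.164) and BUB1B (0.210), and without CRPC C1-3 for RRM2 (0.166). The batch term ended the calls of MKI67 (0.072), HMMR (0.054) and AURKA (0.054). Over all alternatives the adjusted p of MKI67 ran from 2.1e-08 to 0.310, the highest without Pre-Cx C1-4.

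Of 24 tested genes of cholesterol and fatty acid synthesis 5 fell, or 10 adjusted over the list alone (camera adjusted p = 3.1e-09, and 0.433 with an estimated correlation). They included SCD (-1.44 ± 0.28), a fatty acid desaturase, HMGCS1 (-1.01 ± 0.23) and ELOVL6 (-0.91 ± 0.21). With the tumour as a block 0 were called, with an adjusted p of 0.167 for SCD, 0.285 for HMGCS1 and 0.218 for ELOVL6. Their calls were lost without either Pre-Cx library or CRPC C3-1, and those of SCD and ELOVL6 without CRPC C1-3, at up to 0.206 for SCD and 0.309 for ELOVL6 (without Pre-Cx C1-4) and 0.331 for HMGCS1 (without CRPC C3-1). The batch term (0.055 and 0.075) and leaving out Abi/Enza-resistant C2-17 (0.060 and 0.057) ended the calls of HMGCS1 and ELOVL6, and leaving out Abi/Enza-resistant C1-4 that of ELOVL6 (0.056).

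Of 15 tested neuroendocrine markers 2 rose, or 3 with 1 lower adjusted over the list alone (camera adjusted p = 0.018, and 0.433 with an estimated correlation). They were the granin genes CHGA (20.2 ± 1.09 to 58.6 ± 9.25 CPM, 1.54 ± 0.22, adjusted p = 0.0043) and SCG2 (1.46 ± 0.45 to 9.80 ± 0.37 CPM, 2.75 ± 0.51, adjusted p = 0.015). CHGB, another granin gene, had a change of 0.62 ± 0.15 (adjusted p = 0.051) and SCGN, a calcium-binding protein of endocrine cells, of -0.93 ± 0.24 (adjusted p = 0.057). Without Pre-Cx C1-4 the list had an adjusted p of 0.057. The call of CHGA was lost without Pre-Cx C3-1 (0.058), CRPC C3-1 (0.064) or Pre-Cx C1-4 (0.070), and that of SCG2 without these (0.078, 0.098 and 0.206) or CRPC C1-3 (0.088).

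The lists of hypoxia and glycolysis (camera adjusted p = 1.7e-05), the unfolded protein response (0.0175) and oxidative phosphorylation (0.020) lay lower in CRPC, with 0, 1 and 0 members called and 0, 1 and 0 adjusted over the list alone. The called member was TRIB3, a stress-induced pseudokinase chosen after its values were seen (-0.99 ± 0.20, adjusted p = 0.023, and 0.195 with the tumour as a block). It lost its call without Pre-Cx C3-1 (0.084), CRPC C3-1 (0.203), CRPC C1-3 (0.139) or Pre-Cx C1-4 (0.226). None of these calls held with an estimated correlation (adjusted p = 0.507, 0.575 and 0.575). The call of the unfolded protein response was lost with the tumour as a block (adjusted p = 0.196) and without Pre-Cx C1-4 (0.766), and that of oxidative phosphorylation without CRPC C3-1 (0.492) or Pre-Cx C1-4 (0.234). With the block, the immediate early genes lay higher in CRPC (adjusted p = 0.027, against 0.0735 without it), as they did without Pre-Cx C3-1 (0.037) or CRPC C1-3 (0.046). Of the 24 lists 15 did not pass, with adjusted p between 0.0685 and 0.893. Glucocorticoid-induced genes were among these (0.240), with 2 of 18 higher and 1 lower, or 2 and 1 adjusted over the list alone. The transcription factor genes KLF9 (1.76 ± 0.30) and KLF15 (1.19 ± 0.26), both chosen after their values were seen, were the higher ones, and with the block KLF15 had an adjusted p of 0.181. Without Pre-Cx C3-1, CRPC C3-1 or Pre-Cx C1-4 neither was called (0.093, 0.111 and 0.084 for KLF9, and 0.204, 0.196 and 0.102 for KLF15), nor was KLF15 without CRPC C1-3 (0.149). Fibroblast markers lay at a mean log2 CPM of 3.88 in CRPC C3-1 and 2.62 in CRPC C1-3, against 2.82 and 2.80 in the Pre-Cx libraries. Without CRPC C1-3, fibroblast markers (adjusted p = 3.0e-05, against 0.177 with it), epithelial-mesenchymal transition (2.8e-06, against 0.240) and endothelial markers (0.013, against 0.0685) passed, the first 2 as higher and the last as lower.

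**Figure D2:**
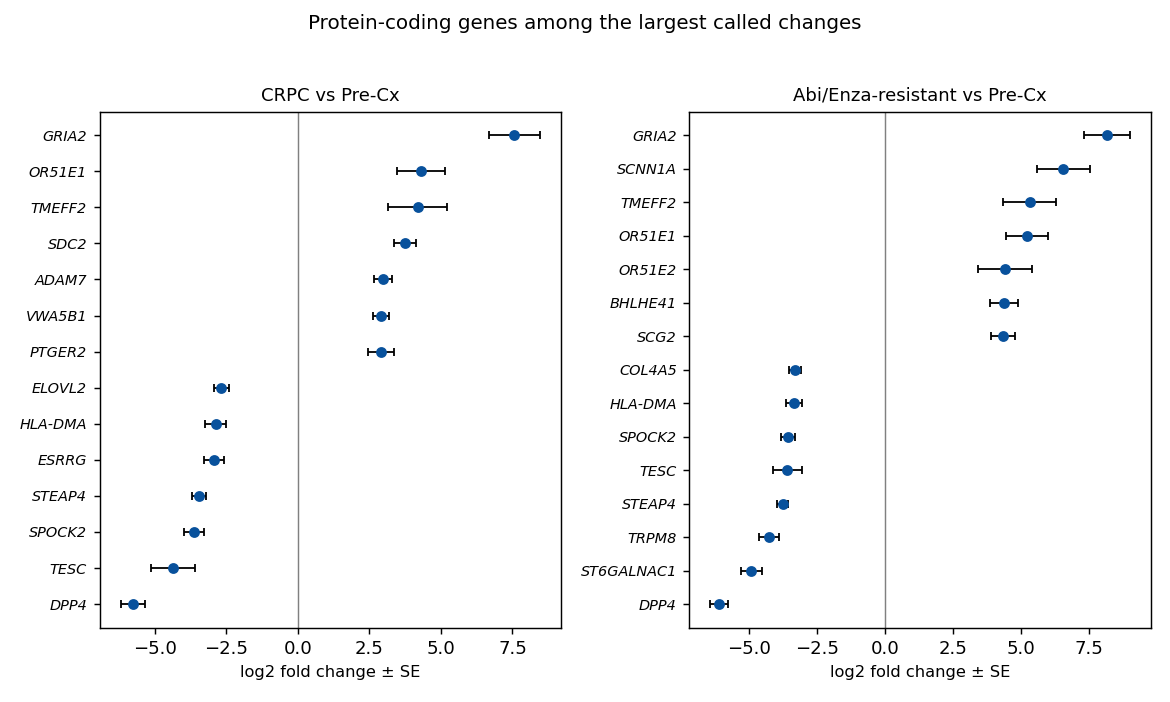
Log2 fold change ± SE of protein-coding genes among the 8 largest called increases and the 8 largest called decreases in CRPC (left) and in Abi/Enza-resistant tumours (right), both against Pre-Cx. GRIA2 is the largest increase in both, at 7.57 and 8.14, and DPP4 the largest decrease, at -5.76 and -6.08.

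The second comparison asks what differs between tumours relapsed on both drugs and tumours relapsed after castration alone. No gene passed edgeR's test, where the smallest adjusted p was 0.135 and 1973 genes had an unadjusted p under 0.05, while DESeq2 called 57, 35 higher and 22 lower. With no filter on low counts edgeR called 544, 300 higher and 244 lower. Genes of hypoxia and glycolysis and glucocorticoid-induced genes lay higher as lists, and markers of fibroblasts lay lower. These list calls were lost with an estimated correlation (adjusted p = 0.443, 0.429 and 0.443), and that of fibroblast markers also without CRPC C3-1 (0.697).

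KLK3 stood at 749 ± 669 CPM (SD, n = 4) against 165 ± 8.88 in CRPC (log2 change 2.19 ± 0.61, adjusted p = 0.296), with 1736 CPM in C3-1 and 276 to 579 in the other 3 libraries. Without Abi/Enza-resistant C3-1 its change was 1.34, with an adjusted p of 0.013, in a range over alternatives of 5.5e-32 to 0.897. FKBP5 (0.73 ± 0.22), TMPRSS2 (0.37 ± 0.19), ERG (-0.21 ± 0.15), AKR1C3 (0.23 ± 0.36), NR3C1 (-0.22 ± 0.53), DPP4 (-0.32 ± 0.54), MKI67 (0.06 ± 0.22) and CHGA (0.33 ± 0.18) had adjusted p between 0.320 and 0.939. CYP17A1 had 3 reads in the 4 libraries and 1 in CRPC.

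Of 42 androgen-induced genes 0 were called, or 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.405). The members with the smallest p were TRPM8, a cold-sensing ion channel (166 ± 8.76 to 39.4 ± 23.3 CPM, -2.09 ± 0.35, adjusted p = 0.186), ACP3, prostatic acid phosphatase (0.69 ± 0.17), HPGD, which breaks down prostaglandins (0.98 ± 0.27), and KLK3. TRPM8 was called with the tumour as a block (-2.71, adjusted p = 0.048), as was SCNN1A, a sodium channel subunit chosen after its values were seen (3.19, adjusted p = 0.022), and these were the only 2 genes called there. Over all alternatives the adjusted p of TRPM8 ran from 2.1e-37, with no filter on low counts, to 0.897, and that of SCNN1A from 5.6e-29 to 0.897. Both were called without Abi/Enza-resistant C3-1 (adjusted p = 0.0054 and 0.023), and TRPM8 also without Abi/Enza-resistant C2-17 (0.0099).

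Of 24 genes of hypoxia and glycolysis 23 had a positive change, 0 were called, and 14 were higher adjusted over the list alone (camera adjusted p = 5.1e-13, lost with an estimated correlation, adjusted p = 0.443). The glycolytic genes TPI1 (0.69 ± 0.19), ALDOA (0.93 ± 0.25), ALDOC (1.19 ± 0.33) and GAPDH (0.78 ± 0.23) had the smallest p. The list stood at a mean log2 CPM of 6.24 ± 0.26 in Pre-Cx, 5.68 ± 0.17 in CRPC and 6.29 ± 0.35 in Abi/Enza-resistant libraries. Of 18 glucocorticoid-induced genes 0 were called and 5 were higher adjusted over the list alone (camera adjusted p = 0.0065, lost with an estimated correlation, adjusted p = 0.429, and without CRPC C1-3, adjusted p = 0.068). They included DDIT4 (0.94 ± 0.15), an inhibitor of mTOR signalling, the metallothioneins MT1X (1.40 ± 0.28) and MT2A (0.88 ± 0.23), and KLF9 (0.87 ± 0.22), a zinc finger factor. DDIT4 (adjusted p = 0.015), MT1X (0.044) and KLF9 (0.021) were called without Abi/Enza-resistant C3-1, and over all alternatives the adjusted p of each reached 0.897.

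Fibroblast markers lay lower (camera adjusted p = 2.2e-05, and 0.443 with an estimated correlation), with 0 of 12 called and 4 lower adjusted over the list alone. FBN1, a microfibril protein, had a change of -1.15 ± 0.33, the collagen genes COL3A1 and COL1A1 of -2.53 ± 0.78 and -1.88 ± 0.58, and MMP2, a matrix protease, of -1.97 ± 0.70. The list of epithelial-mesenchymal transition did likewise (camera adjusted p = 0.0067, and 0.443 with an estimated correlation), with 0 of 5 called and 2 lower adjusted over the list alone, ZEB2 (-3.31 ± 0.77), a zinc finger repressor, and MMP2. FN1 (-0.38 ± 0.22), a matrix glycoprotein, and ITGA5 (-0.40 ± 0.46), an integrin subunit, were not lower by this count. CRPC C3-1 held the highest level of both lists, and without it the adjusted p was 0.697 for fibroblast markers and 0.414 for the transition list. The call of the transition list was lost with the batch term too (adjusted p = 0.112).

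Oxidative phosphorylation (camera adjusted p = 3.8e-05), cholesterol and fatty acid synthesis (7.4e-04) and luminal markers (0.040) lay higher, with 0 members called in each and 0, 0 and 1 higher adjusted over the list alone. None held with an estimated correlation (adjusted p = 0.591, 0.608 and 0.591). The first 2 calls were lost without CRPC C3-1 (adjusted p = 0.232 and 0.087), and that of luminal markers with the tumour as a block (0.065), without CRPC C1-3 (0.277) or without Abi/Enza-resistant C1-4 (0.077). All 3 calls were lost with the batch term (adjusted p = 0.07375, 0.07375 and 0.080). With the block, S-phase genes (adjusted p = 1.2e-04, against 0.078 without it) and mitosis genes (2.7e-04, against 0.945) lay lower in Abi/Enza-resistant tumours. S-phase genes did so also with the batch term (0.0023) and without CRPC C3-1 (0.017), Abi/Enza-resistant C2-17 (0.015) or Abi/Enza-resistant C1-4 (0.010). The mitosis list went the other way without Abi/Enza-resistant C1-3, where it lay higher (0.026). Over the alternatives the adjusted p ran from 1.2e-04 to 0.775 for S-phase and from 2.7e-04 to 0.981 for mitosis. The other 17 lists did not pass, with adjusted p between 0.078 and 0.945. Of these, neuroendocrine markers passed as higher without Abi/Enza-resistant C2-17 (0.028), the unfolded protein response as higher without Abi/Enza-resistant C1-3 (0.030), endothelial markers as lower without CRPC C3-1 (0.017) and ribosomal proteins as higher without CRPC C1-3 (3.5e-04) or Abi/Enza-resistant C3-1 (3.8e-04).

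The number of called genes was 81 without Abi/Enza-resistant C3-1, 10 without CRPC C1-3 and 2 without Abi/Enza-resistant C2-17. Without Abi/Enza-resistant C3-1 and CRPC C3-1 together, a choice made after seeing the data, it was 6. The 2 genes were TRPM8 (-2.53, adjusted p = 0.0099) and MCC (-1.87, adjusted p = 0.0099), a colorectal tumour suppressor candidate chosen after its values were seen.

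**Figure D3:**
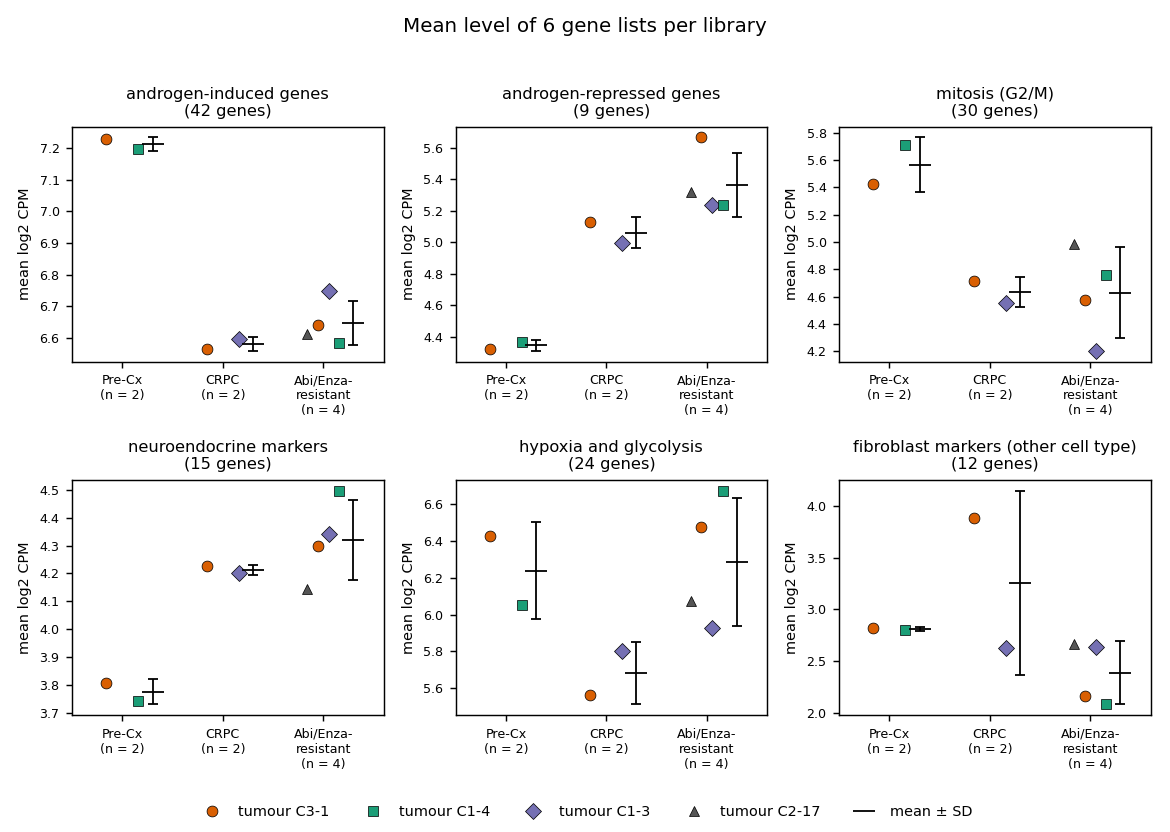
Mean log2 CPM of 6 gene lists in each of the 8 libraries, with tumours as symbols and the mean ± SD of each group beside them. The androgen-induced list lies at 7.23 and 7.20 in Pre-Cx and between 6.57 and 6.75 in the other 6 libraries, and fibroblast markers are highest in CRPC C3-1, at 3.88.

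The third comparison sets tumours relapsed on both drugs against tumours before castration. DPP4 fell from 148 ± 5.93 (SD, n = 2) to 2.03 ± 1.62 CPM (SD, n = 4), a log2 change of -6.08 ± 0.32 (adjusted p = 2.2e-06). Most genes of S-phase and mitosis fell, 16 androgen-induced genes fell while 7 rose, and the granin genes CHGA, CHGB and SCG2 rose. Glucocorticoid-induced genes lay higher as a list, a call lost with an estimated correlation (adjusted p = 0.166).

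In all, 2169 genes were called, 985 higher and 1184 lower, of which 566 and 521 changed more than 2-fold, and 4599 had an unadjusted p under 0.05. Of these, 2162 showed no overlap between the libraries of both groups, a state found in 36.1% of tested genes and given by chance to 13.3%. The count was 836 without Pre-Cx C3-1, 389 without Pre-Cx C1-4 and 1184 with the file naming pattern as a batch term. Without CRPC C3-1 and Abi/Enza-resistant C3-1 together, chosen after seeing the data, it was 2912.

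The largest increases among abundant coding genes included those of GRIA2 (8.14 ± 0.84), SCNN1A (6.56 ± 0.97), TMEFF2 (5.31 ± 0.98), OR51E1 (5.22 ± 0.79), OR51E2 (4.42 ± 0.98), the neighbour and paralog of OR51E1, BHLHE41 (4.36 ± 0.51), a circadian repressor, and SCG2 (4.33 ± 0.43). The largest decreases after DPP4 were those of ST6GALNAC1 (-4.90 ± 0.39), a sialyltransferase, TRPM8 (-4.25 ± 0.35), STEAP4 (-3.76 ± 0.20), TESC (-3.59 ± 0.53), SPOCK2 (-3.56 ± 0.27), HLA-DMA (-3.34 ± 0.29) and COL4A5 (-3.31 ± 0.22), a basement membrane collagen. The highest adjusted p of these was 0.014, for OR51E2. With the tumour as a block OR51E2 had a change of 3.50 and was not called (adjusted p = 0.065), and over its alternatives the adjusted p ran from 8.1e-51 to 0.154, with a loss also under the batch term (0.058). Without Pre-Cx C1-4 the calls of SCNN1A (adjusted p = 0.051), TMEFF2 (0.100), OR51E1 (0.054) and OR51E2 (0.154) were lost, and without Pre-Cx C3-1 those of TMEFF2 (0.065) and OR51E2 (0.115). Of the 43 called genes that the rule takes for this comparison 25 kept their call without each library in turn, against 25 without Pre-Cx C1-4 and 34 without Pre-Cx C3-1.

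Among 42 androgen-induced genes, 16 fell and 7 rose, or 20 and 7 adjusted over the list alone (camera adjusted p = 7.1e-10, and 0.0157 with an estimated correlation). The glandular protease gene KLK2 fell (-0.94 ± 0.17, chosen after its values were seen). STEAP4, TRPM8, NCAPD3 (-1.79 ± 0.12) and SLC43A1 (-2.64 ± 0.22), an amino acid transporter, had the smallest p. The members that rose were KLK3 (2.35 ± 0.62, adjusted p = 0.030) and, chosen after their values were seen, ADAM7 (2.84), STEAP2 (1.58), PLPP1 (1.56), ELL2 (1.27), ACP3 (1.19) and KLK4 (0.98), which are a metalloreductase (STEAP2), a lipid phosphatase (PLPP1), an elongation factor (ELL2), a phosphatase (ACP3) and a protease (KLK4) of the prostate or its secretion. Of these, the calls of PLPP1 without Pre-Cx C3-1 (adjusted p = 0.078), ELL2 without Pre-Cx C1-4 (0.078) and KLK4 without either (0.137 and 0.259) or with the batch term (0.123) were lost, as was that of KLK2 without Pre-Cx C1-4 (0.118). The call of KLK3 was lost with the tumour as a block (adjusted p = 0.083), with the batch term (0.104) and without Pre-Cx C3-1 (0.198), Pre-Cx C1-4 (0.207), CRPC C3-1 (0.0520) or CRPC C1-3 (0.0506), in a range over alternatives of 5.3e-37 to 0.207. FKBP5 stood at 580 ± 174 CPM in Pre-Cx and 379 ± 86.2 (-0.61 ± 0.21, adjusted p = 0.080, and 0.019 with the block). TMPRSS2 (0.11 ± 0.19), ERG (-0.35 ± 0.15), AKR1C3 (0.87 ± 0.38) and NR3C1 (0.66 ± 0.57) were not called, with adjusted p from 0.158 to 0.761, and CYP17A1 had 3 reads against 4. Without Abi/Enza-resistant C3-1, AKR1C3 (1.14, adjusted p = 0.0011) and NR3C1 (1.01, adjusted p = 0.025) were called.

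Of 9 androgen-repressed genes 4 rose, or 5 adjusted over the list alone (camera adjusted p = 1.8e-06, and 0.037 with an estimated correlation). They included TRIB1 (1.76 ± 0.20), OPRK1 (1.52 ± 0.26) and CAMK2N1 (1.49 ± 0.41, adjusted p = 0.035), the last not called with the tumour as a block (1.38, adjusted p = 0.156). Without Pre-Cx C1-4 the calls of OPRK1 (0.076) and CAMK2N1 (0.289) were lost, and that of CAMK2N1 also with DESeq2 (0.053) and without Pre-Cx C3-1 (0.148) or Abi/Enza-resistant C2-17 (0.075), C1-3 (0.068) or C1-4 (0.072). In Abi/Enza-resistant C3-1, TRIB1 and CAMK2N1 lay below and OPRK1 above the other 3 libraries of the group.

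Of 29 genes of S-phase 26 fell, or 28 with 1 higher adjusted over the list alone, and of 30 of mitosis 26 fell, or 30 adjusted over the list alone. The camera adjusted p was 1.7e-20 and 8.3e-19, and both were lost with an estimated correlation (adjusted p = 0.241 for each) but not with fry (0.012 and 0.023). TK1 (-1.35 ± 0.16), MCM7 (-0.86 ± 0.12), MCM5 (-1.33 ± 0.18), CDC45 (-1.28 ± 0.18), a helicase cofactor, AURKA (-0.96 ± 0.16), TPX2 (-1.02 ± 0.17), BUB1B (-0.99 ± 0.17) and HMMR (-1.33 ± 0.24) were the members with the smallest p, and MKI67 fell from 336 ± 52.1 to 164 ± 41.2 CPM (-1.04 ± 0.21, adjusted p = 0.0082). Without Pre-Cx C1-4 the adjusted p of MKI67 was 0.141 and the calls of AURKA (0.092), TPX2 (0.084), BUB1B (0.054) and HMMR (0.119) were lost too. With the batch term 12 genes of mitosis were called, against 25 with the tumour as a block.

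Of 15 neuroendocrine markers 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.0063, 0.241 with an estimated correlation and 0.016 with fry). CHGA reached 73.4 ± 13.8 CPM (1.87 ± 0.20, adjusted p = 2.4e-04), SCG2 29.4 ± 11.3 CPM (4.33 ± 0.43, adjusted p = 1.5e-04) and CHGB 53.9 ± 4.74 CPM (0.92 ± 0.14, adjusted p = 0.0016). SYT1, a synaptic vesicle protein, fell (-1.88 ± 0.45, adjusted p = 0.020), with no call with the tumour as a block (-1.75, adjusted p = 0.069), with the batch term (0.055) and without Pre-Cx C3-1 (0.103) or Pre-Cx C1-4 (0.189). Chosen after their values were seen, ENO2 had a change of 1.47 and SCGN of -0.66, and their highest adjusted p over the alternatives was 0.287 and 0.232. ENO2 was not called with the batch term (adjusted p = 0.101) or without Pre-Cx C3-1 (0.110), Pre-Cx C1-4 (0.287), CRPC C3-1 (0.0504) or Abi/Enza-resistant C1-4 (0.065). SCGN was not called with the tumour as a block (adjusted p = 0.135), with the batch term (0.112) or, at 0.065 to 0.232, without any 1 library other than Abi/Enza-resistant C3-1.

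Of 18 glucocorticoid-induced genes 6 rose, or 6 with 2 lower adjusted over the list alone (camera adjusted p = 0.0064, 0.166 with an estimated correlation and 0.016 with fry). They included KLF9 (2.63 ± 0.27), DDIT4 (0.96 ± 0.15), MT1X (1.54 ± 0.28) and MT2A (1.00 ± 0.23), with adjusted p from 1.6e-04 to 0.016, and the circadian gene PER1, chosen after its values were seen (1.19 ± 0.30), whose call was lost with the batch term (0.082) and without Pre-Cx C3-1 (0.103) or Pre-Cx C1-4 (0.248). The calls of MT1X and MT2A were lost without Pre-Cx C3-1 (adjusted p = 0.063 and 0.109) or Pre-Cx C1-4 (0.065 and 0.172), and that of DDIT4 without Pre-Cx C1-4 (0.054). Of 17 genes of steroid synthesis and androgen metabolism 1 rose and 2 fell, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.676). HSD17B4 (0.82 ± 0.18) and HSD17B11 (-1.10 ± 0.18), steroid dehydrogenases, and UGT2B7 (-2.90 ± 0.47), which conjugates steroids and has close paralogs, were called, and AKR1C2 (-1.18 ± 0.39, adjusted p = 0.073) was not. The call of HSD17B4 was lost with the batch term (0.063) and without Pre-Cx C3-1 (0.163) or Pre-Cx C1-4 (0.076).

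Cholesterol and fatty acid synthesis lay lower (camera adjusted p = 0.0057), with 2 of 24 called, or 6 adjusted over the list alone, and its call was lost with an estimated correlation (adjusted p = 0.908), with the tumour as a block (0.192), without Abi/Enza-resistant C2-17 (0.0573) and without Pre-Cx C1-4 (0.0580). The called members included, chosen after its values were seen, SCD (-0.86 ± 0.23), with an adjusted p of 0.119 with the block and 0.069 with the batch term, and with no call without Pre-Cx C3-1 (0.085), Pre-Cx C1-4 (0.320), CRPC C3-1 (0.056), CRPC C1-3 (0.058) or Abi/Enza-resistant C2-17 (0.078). Of 6 endothelial markers 2 fell, or 2 adjusted over the list alone (camera adjusted p = 0.0064, 0.241 with an estimated correlation and 0.016 with fry). They were VWF, a clotting factor carrier (9.61 ± 1.22 to 1.09 ± 0.52 CPM, -3.17 ± 0.41, adjusted p = 7.7e-04), and MMRN2, a matrix protein of vessels (-1.22 ± 0.26, adjusted p = 0.011, and 0.053 with the tumour as a block, 0.055 without Pre-Cx C3-1 and 0.145 without Pre-Cx C1-4). CLDN5, of endothelial tight junctions, had a change of -0.82 ± 0.33 (adjusted p = 0.133), and ERG, which is also in this list, is expressed by VCaP itself. The other 16 lists had adjusted p between 0.0768 and 0.982. Without Abi/Enza-resistant C3-1, basal markers (0.030), muscle markers (0.032) and the unfolded protein response (0.0023) passed as lower, the last also without Pre-Cx C3-1 (0.0042).

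Both comparisons with Pre-Cx share its 2 libraries. Across genes, which are not independent replicates, their log2 changes correlated at 0.833, against 0.575 in 20 simulations of unchanged groups with shared controls, and their covariance was 0.391 against 0.0810, a difference of 0.310. Of the called genes 221 were higher and 328 lower in both, and 0 went opposite ways. Independent lists would share 13.8 and 24.4, a value that leaves out the shared controls. The simulations shared 0 and 0, but with 0.65 calls per comparison on average they had almost none to share, so they are no reference for these counts. The controls were not split, as each side would hold 1 library, and part of the excess in these counts may come from the shared controls.

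Several lists passed camera in none of the comparisons, given here in the order CRPC against Pre-Cx, Abi/Enza-resistant against CRPC and Abi/Enza-resistant against Pre-Cx. The camera adjusted p was 0.451, 0.327 and 0.949 for basal markers, 0.893, 0.945 and 0.924 for genes associated with ERG, 0.577, 0.945 and 0.676 for the interferon response, and 0.893, 0.622 and 0.791 for Wnt targets and ligands. It was 0.0735, 0.375 and 0.448 for immediate early genes, 0.893, 0.212 and 0.676 for ribosomal proteins, and 0.430 and 0.945 for steroid metabolism in the first 2 comparisons. Among other cell types it was 0.779, 0.622 and 0.982 for leukocyte markers, 0.138, 0.478 and 0.077 for muscle markers (0.016 with fry in the last comparison, as lower) and 0.893, 0.945 and 0.893 for adipocyte and skin markers. Median, mean and test differed in sign for ERG-associated genes, Wnt targets and ribosomal proteins in the first of these, for ERG-associated genes, interferon response, muscle and adipocyte markers in the next, and for Wnt targets and leukocyte markers in the last. Erythroid markers had 1 tested member and mitochondrially encoded mRNAs 0, so neither was tested.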

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

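For the Abi/Enza-resistant library of tumour C3-1, the tests of depth, of other cell types and of cells other than VCaP were chosen only after the result was seen, and the test of chromosome segments was not. Among 101 values compared over the 4 Abi/Enza-resistant libraries, 9 held a library whose gap to the nearest of the others, divided by the whole range, exceeded the critical value of Dixon's ratio for 4 values. Chance gives this in about 1 of 20 groups, or 5 values here, and 7 of the 9 lay in C3-1.

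In C3-1 the value was lowest for TRIB1 (ratio 0.836, 313 against 480 to 512 CPM), CAMK2N1 (0.85, 213 against 568 to 631 CPM) and VWF (0.832, 0.314 against 1.24 to 1.43 CPM, where 0.314 is under the 3-count floor of 0.469 CPM of that library). It was highest there for TESC (0.886, 10.98 against 1.24 to 2.35 CPM), OPRK1 (0.971, 34.2 against 20.7 to 21.1 CPM), SCGN (0.853, 71.0 against 42.3 to 46.5 CPM) and the list of the unfolded protein response (0.867, a mean log2 CPM of 6.22 against 5.55 to 5.64). GRIA2 was lowest in C2-17 (0.919, 60.9 against 140 to 147 CPM), and CLDN5 was lowest in C1-3 (0.928, 1.56 against 2.98 to 3.09 CPM).

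In C3-1, 112 of 13864 genes lay over 2 log2 units from the mean of the other 3 libraries, against 7, 6 and 2 in those. The tables argue against depth, since 119 genes lay so far after thinning to 4235791 counts. They also argue against cells other than VCaP, since ERG stood at 0.870 and TMPRSS2 at 1.47 of the lowest of the other 7 libraries. For RNA from other cell types, the largest excess over 5 lists was 0.0557 in mean log2 CPM. This cannot decide, as the counts are of human genes and RNA of the mouse host could be missed. Few list members were tested too, with 4 of 20 leukocyte and 3 of 14 adipocyte and skin markers. Gained or lost chromosome segments in this biopsy may account for smaller shifts shared by neighbouring genes. The spread of medians over windows of 50 neighbouring genes was 3.19 times that of shuffled orders, against 2.69, 1.94 and 2.27 in the other libraries. Window medians ran from -0.750 to 0.559 log2 units in C3-1, against -0.339 to 0.389, -0.220 to 0.295 and -0.182 to 0.255 in those. The 10 windows of C3-1 furthest from the median of its genes lay on 5 chromosomes, and 9 of them adjoined another. Among blocks picked for this shift, ZNF596 to EIF4EBP1 had a median of -0.635 in C3-1 and MYBBP1A to TRIM16 of 0.504. The other 7 libraries lay at -0.0654 to 0.0578 and at -0.0648 to 0.0576 there. Medians of this size do not reach the 2 log2 units of the genes counted above. A window median does not bound the change of a single gene, however. Whether the genes counted above lie in the shifted windows was not tested. DNA copy number was not analysed here, and a biological difference between tumours stays open and untested.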

How the results depend on the processing

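The alternatives were planned except leaving out CRPC C3-1 and Abi/Enza-resistant C3-1 together, a test chosen only after the result was seen. In CRPC against Pre-Cx the 595 genes became 1596 with no filter on low counts, 156 with the tumour as a block and 1974 with only the libraries of both groups, and 58 to 1588 leaving out 1 library. In Abi/Enza-resistant against CRPC the 0 genes became 57 with DESeq2, 544 with no filter, 2 with the block, 6 without both libraries named above, and 0 to 81 leaving out 1 library, the 81 without Abi/Enza-resistant C3-1. With all libraries edgeR gave 1973 genes an unadjusted p under 0.05. In Abi/Enza-resistant against Pre-Cx the 2169 genes became 3258 with no filter, 1184 with the batch term, and 389 (without Pre-Cx C1-4) to 2962 leaving out 1 library. The other counts stayed within 1.5 times. Abi/Enza-resistant C3-1 is in neither group of CRPC against Pre-Cx. Leaving it out can thus change that count only through the shared estimate of the spread, the filter or the scaling. Which of these acted, and the cause of the other changes, was not tested. The mitosis list turned from higher to lower in Abi/Enza-resistant against CRPC with the block (adjusted p = 2.7e-04), and NRCAM, a cell adhesion gene chosen after its values were seen, turned from 0.34 to -1.25 without Abi/Enza-resistant C3-1 (adjusted p = 0.0054, in a range of 0.0054 to 0.988) and stood at 0.63 without C2-17. For genes named by rule, 1782 values kept their side of the threshold, 157 lost and 53 gained a call, and for lists 855, 55 and 22. Direction was compared only where the main fit or the alternative made a call. Values kept without a call could therefore change sign, as KLK3 did in CRPC against Pre-Cx (-0.218 to 0.300 over the alternatives). A DESeq2 value without an adjusted p was counted as kept. For genes chosen after their values were seen, 456 values kept their side of the threshold, 102 lost and 11 gained a call, and 1 turned direction. With fry, 7 list calls were lost in CRPC against Pre-Cx and 7 in Abi/Enza-resistant against CRPC. In Abi/Enza-resistant against Pre-Cx fry lost 1 list call and gained 1, that of muscle markers. The androgen-induced list kept its call in CRPC (adjusted p 6.4e-18 to 0.0065) and Abi/Enza-resistant (8.7e-12 to 0.0157) against Pre-Cx. List levels moved by more than 1 SD in 22 of the values, and 128 did not. Leaving out a library of a pair leaves 1 library, assumed to vary like the other groups. With 4105435 to 6396196 counts, genes below 0.469 to 0.731 CPM lie under the 3-count floor.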

Other observations

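For the olfactory receptor genes, all tests but that over the other genes of the stretch were chosen only after the result was seen. Some lists that did not move as a whole held members that changed both ways in Abi/Enza-resistant against Pre-Cx, all chosen after their values were seen. Of 23 interferon response genes 3 rose and 3 fell, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.676). IFI35 (2.53) and B2M (1.24) were among those that rose, and TAP1 (-1.37), a peptide transporter, OAS3 (-0.64) and IRF9 (-0.87), an interferon-activated factor, fell. Of 19 luminal genes 2 rose and 2 fell (camera adjusted p = 0.924), with FOLH1 (3.83), prostate-specific membrane antigen, and ACP3 (1.19) higher and SPDEF (-1.05) and ESRP1 (-0.67) lower. Of 8 basal genes 2 rose and 2 fell (camera adjusted p = 0.949), with CD44 (2.48) and DST (0.40) higher and KRT14 (-3.34) and COL17A1 (-1.39) lower. Without Pre-Cx C1-4 ACP3, SPDEF and CD44 kept their call, and the adjusted p of the others lay between 0.0537 for KRT14 and 0.437 for OAS3. Without Pre-Cx C3-1 the calls of IFI35 (0.149), B2M (0.052), IRF9 (0.095), FOLH1 (0.060), DST (0.166) and COL17A1 (0.183) were lost. Those of IRF9 (0.062 and 0.065), DST (0.073 and 0.070) and COL17A1 (0.0515 and 0.0524) were lost without CRPC C3-1 and without CRPC C1-3. Leaving out Abi/Enza-resistant C2-17 ended those of OAS3 (0.0513), IRF9 (0.087) and COL17A1 (0.059), leaving out C1-3 of that group those of TAP1 (0.063), OAS3 (0.062), DST (0.083) and COL17A1 (0.065), and leaving out C1-4 of that group those of OAS3 (0.060), IRF9 (0.1005) and DST (0.070). TAP1 (adjusted p = 0.072), OAS3 (0.117), FOLH1 (0.073), DST (0.112) and COL17A1 (0.112) were not called with the tumour as a block.

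OR51E1 and OR51E2 lie in a stretch of 61 genes, and 13 consecutive genes with at least 10 reads, from OR51D1 to OR51T1, were at least 4-fold higher over the pooled libraries after castration, against a longest run of 4 in 1000 shuffled orders, which argues against a chance neighbourhood. Reads shared between receptor copies stay open. The 18 genes of the stretch that are not olfactory receptors had a summed ratio of 0.868 (counting interval 0.837 to 0.899), as written before for that explanation. Genes outside the run hold most of these reads, so this ratio cannot decide on sharing between receptors. The 2 genes inside the run that are not olfactory receptors went from 1 to 85 reads (ratio 27.4), a void test, as the run was chosen for being higher. The 529 olfactory receptor genes outside the stretch stood at a summed 156.2 CPM in Pre-Cx and 156.8 CPM after castration. No summed rise was thus seen there, but sharing among the copies of the stretch was not tested. On transcription of the whole stretch, 75% of the 32 stretch genes with at least 10 reads were higher, which decides neither way. Those that were lower all lie before OR51D1, among them NUP98 (188 to 157 CPM), STIM1 (33.4 to 24.2 CPM) and TRIM68 (44.4 to 34.6 CPM). They argue against a rise of the whole stretch, though PGAP2, RHOG and AC087441.1 on that side were higher. From OR51D1 on, every gene with at least 10 reads was higher, so transcription of that part stays open. The summed CPM of the receptor genes of the stretch was 16.3 and 12.7 in Pre-Cx C3-1 and C1-4, 102 and 132 in CRPC, and 301, 38.7, 391 and 177 in Abi/Enza-resistant C2-17, C3-1, C1-3 and C1-4. Without OR51E1 and OR51E2 it was 6.74 in Abi/Enza-resistant C3-1, against 10.5 and 7.80 in Pre-Cx. Without these genes it was 30.8 and 58.5 in CRPC C3-1 and C1-3, and 91.8, 117.5 and 54.7 in Abi/Enza-resistant C2-17, C1-3 and C1-4.

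ZEB2 stood at 66.1 CPM in CRPC C3-1 and 3.43 CPM in CRPC C1-3, and its level in the other 6 libraries lay between 1.59 and 6.85 CPM. The ZEB2 change in Abi/Enza-resistant against CRPC was -4.24 without CRPC C1-3 (adjusted p = 0.0023, in a range over alternatives of 1.9e-33 to 0.998) and 0.01 without CRPC C3-1 (adjusted p = 0.998).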
